A study of Danio rerio with 12 samples.

How the data were processed

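RNA was measured by sequencing of polyA RNA in 12 zebrafish libraries, made from whole brain and from fin of scn8ab(temca) mutants and their siblings held at 33 °C. Brain was taken after 1 day at 33 °C, and uninjured and amputated fin alike after 36 hours. The 12 libraries formed 6 groups of 2: mutant and control brain, mutant and control uninjured fin, and mutant and control fin at 36 hours post-amputation (hpa). The labels give the control genotype as wild-type, while the names of the control libraries carry the tag HET, and the sources used here do not settle which holds. Each file held deposited raw read counts per gene for 32520 Ensembl genes, which the authors had not normalised. Per the submitters' processing notes, reads were trimmed with cutadapt, aligned with HISAT2 to GRCz11 and counted with featureCounts. The versions, the strand setting and the annotation release are not given in the sources used here.

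Gene symbols came from a table pairing Ensembl IDs with symbols, in which 29201 of the 32520 IDs had a symbol and 1719 symbols were shared by more than 1 gene. For a shared symbol the Ensembl ID is given. The symbol SCN8A belonged to 2 genes, and the table does not say which of them is scn8ab, so both are given. The genome of the authors' build was not among the sources used here. Gene neighbourhood came from a table of another assembly, so no coordinates are given.

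Counts were analysed in R 4.3.3. In edgeR 4.0.16, genes were filtered with filterByExpr, libraries were scaled by TMM, and groups were compared by the two-sided quasi-likelihood F-test with Benjamini-Hochberg adjustment, with calls at an adjusted p under 0.05. Brain was fitted from its 4 libraries (21917 genes tested, 2 residual degrees of freedom) and fin from its 8 libraries in 1 fit (21220 genes, 4 residual degrees of freedom). The biological coefficient of variation was 0.225 in brain and 0.221 in fin. CPM are counts scaled by the TMM-scaled library size, given as mean ± SD of 2 libraries. Log2 fold changes are given with their SE. Library totals ran from 52.3 M to 73.3 M counts. Floors cover counting error only, and intervals of odds ratios take genes as independent units. A fold against a group at 0 was computed as a lower bound, with 3 counts over the group as the floor.

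The groups, the 6 comparisons, 46 gene lists (signalling pathways, cell types, channels and synapses, stress responses and metabolism), the tests and the alternatives were chosen before the data were examined. Lists with at least 5 tested members were tested with camera at a preset inter-gene correlation of 0.01, adjusted over the lists of a comparison. Camera with an estimated correlation and fry, from limma 3.58.1, were the alternatives. The 2 camera settings differed in more than the correlation. For the glucocorticoid list in brain the estimated correlation was 0.00943, near the preset, yet the unadjusted camera p went from 0.000243 to 0.066. For immediate early genes at 36 hpa it was 0.00893, and the unadjusted camera p went from 6.18e-34 to 0.000246. A higher p with an estimated correlation is thus no measure of the correlation between genes. List members were counted over all genes tested and adjusted over the list alone. The genes named in each comparison were the 8 largest rises and the 8 largest falls among called genes with a mean of at least 5 CPM, no overlap between groups and a symbol that is not a clone name, then up to 4 called members per list by smallest adjusted p, then both SCN8A genes. Where fewer than 3 genes passed, the 5 of smallest p are given as not passing. About 20 to 30 of these are named in the text. Members named from a list that had no call over all genes were chosen after their values were seen, and not always by smallest p.

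Alternatives were RLE scaling, library size alone, no filter on low counts, removal of mitochondrial and hemoglobin genes, limma-voom, the DESeq2 1.42.0 Wald test, 1 fit of all 12 libraries, a fit of the 4 libraries compared, a replicate block, an absolute log2 fold change of at least 1, and each library left out in turn. With 2 libraries per group, leaving out 1 left a lone library that was assumed to vary like the other groups. Uninjured and 36 hpa fin libraries share pool tags. The residuals of libraries with the same tag correlated across genes at 0.170 in mutants and 0.269 in controls, so the tag was treated as pairing them and used as a block in an alternative. These are only 2 independent correlations. The design of the neighbourhood test had named windows of 10 Mb, but with no coordinates of the authors' build the 50 nearest placed genes were used instead.

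The method was tested on simulated counts with 100 genes changed 2-fold and 100 changed 4-fold in each comparison. It recovered 60 and 79 of these in brain, with 22 false calls among 161. In uninjured fin it recovered 41 and 82, with 11 false calls among 134. In fin at 36 hpa it recovered 40 and 94, with 10 among 144. For amputation in control fin it recovered 36 and 88, with 15 false calls among 139. For amputation in mutant fin it recovered 34 and 89, with 12 among 135. For the difference between the responses it recovered 9 and 65, with 4 among 78. The share of false calls was above the adjusted p threshold in each simulation, narrowly so for the difference between the responses. Each simulation changed only 200 genes, while amputation gave 9430 calls in control fin and 9612 in mutant fin. The simulated recovery for amputation thus cannot be carried over to the real counts. Groups of 2 libraries are too small for a test of other splits of the samples. No library was left out of the comparisons.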

Results

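The data comprise 12 libraries of polyA RNA from adult zebrafish of the Ekkwill strain, with 2 libraries in each of 6 groups. The mutants carried scn8ab(temca) on both copies of a voltage-gated sodium channel gene, and the controls were siblings. Total counts were 59.3 M and 70.8 M in mutant brain, and 58.0 M and 55.0 M in control brain. Uninjured fin had 65.6 M and 66.4 M counts in mutants, and 73.3 M and 52.3 M in controls. Fin at 36 hours post-amputation (hpa) had 60.0 M and 66.4 M in mutants, and 67.1 M and 62.5 M in controls. In fin the first principal component held 71.0% of the variance and separated amputated from uninjured libraries. The second held 7.31% and parted the control libraries within a group, at -56.3 and 41.6 in uninjured fin and -38.4 and 14.9 at 36 hpa. In brain the first component held 49.98% and separated the genotypes, and the second held 31.1% and parted the mutant libraries, at 46.3 and -55.7. The keratin gene krt5 took 2.62% to 2.97% of counts at 36 hpa and 5.31% to 7.15% in uninjured fin.

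The 2 genes with the symbol SCN8A were abundant in brain and near the floor in fin. In brain, ENSDARG00000005775 stood at 453 ± 25.1 CPM in mutants and 410 ± 63.1 in controls (log2 fold change 0.15, SE 0.12, adjusted p = 0.523, and 0.00543 to 0.299 with 1 library left out, lowest without control 2 and highest without control 1), and ENSDARG00000018032 at 159 ± 3.62 and 122 ± 16.1 (0.37, SE 0.11, adjusted p = 0.151). In fin, ENSDARG00000018032 stood at 0.194 ± 0.0930 CPM in uninjured mutants and 0.211 ± 0.0623 in uninjured controls, and at 0.266 ± 0.0682 and 0.295 ± 0.141 at 36 hpa. A genotype difference in fin was not detectable at this depth. ENSDARG00000005775 had 0 to 6 counts per fin library (0 and 0 in uninjured mutants, 4 and 2 in uninjured controls) and was not tested there. The edgeR test with Benjamini-Hochberg adjustment passed neither gene in brain, nor ENSDARG00000018032 in uninjured fin (adjusted p = 0.979) or at 36 hpa (adjusted p = 0.995), and DESeq2 passed ENSDARG00000018032 in brain (adjusted p = 0.0269).

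The brain comparison asks how mutant and control brain differ after 1 day at 33 °C. Several chaperone genes rose in mutant brain. The inducible chaperone gene hsp70l stood at 66.5 ± 9.40 CPM against 8.40 ± 2.91 (log2 fold change 2.98, SE 0.26, adjusted p = 0.0365), and hsp70.3 at 55.3 ± 2.43 against 18.8 ± 1.25 (1.56, SE 0.10, adjusted p = 0.0178). SERPINH1 ENSDARG00000019949, a collagen chaperone gene, rose from 8.004 ± 0.344 to 86.5 ± 23.6 CPM (3.43, SE 0.22, adjusted p = 0.0171). The chaperone gene HSPA2 rose as well, by a log2 fold change of 2.53 (SE 0.20, adjusted p = 0.025). Of 42 heat shock genes, 3 rose over all genes tested, and 11 rose and 4 fell adjusted over the list alone (camera adjusted p = 0.000768, and adjusted p = 0.798 with an estimated correlation). The median of this list was 0.01 and its mean 0.32, and with 1 library left out the median ranged from -0.02 to 0.04.

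**Figure D1:**
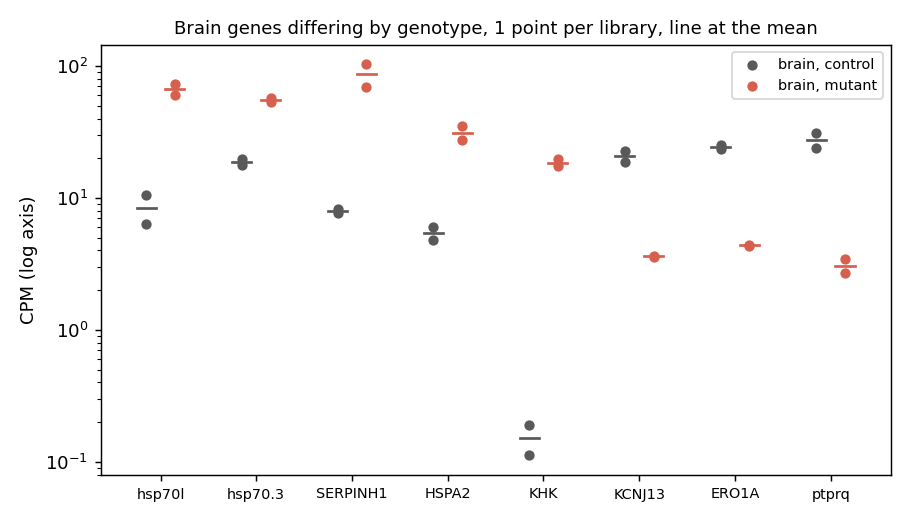
CPM on a log axis of 8 genes that differed between mutant and control brain, with 1 point per library and a line at the mean of the 2 libraries. The mutant libraries lie above the control libraries for hsp70l, hsp70.3, SERPINH1, HSPA2 and KHK, and below them for KCNJ13, ERO1A and ptprq.

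Further genes rose in mutant brain, some of them from a level close to 0. KHK, which encodes ketohexokinase, stood at 18.5 ± 1.67 CPM against 0.152 ± 0.0557, and the replication gene CDC45 at 31.6 ± 13.5 against 1.16 ± 0.0228. The gene taco1 had 624 and 757 counts in the mutant libraries and 2 counts in each control library. ABCA1, a cholesterol transporter gene, rose from 88.8 ± 3.23 to 164 ± 8.07 CPM (log2 fold change 0.89, SE 0.09, adjusted p = 0.0453). The gene nub1 rose from 6.13 ± 0.614 to 18.2 ± 0.0804 CPM (1.57, SE 0.14, adjusted p = 0.0388). Among the genes that fell, the inward rectifier potassium channel gene KCNJ13 stood at 3.61 ± 0.0405 CPM against 20.8 ± 2.68, and the oxidative folding gene ERO1A at 4.38 ± 0.0203 against 24.3 ± 1.32. The phosphatase gene ptprq fell from 27.5 ± 4.86 to 3.08 ± 0.499 CPM, and the centriole gene cep135 from 54.3 ± 1.82 to 13.8 ± 2.59. CC2D1B, R3HDM2 and pemt fell by log2 fold changes of -1.99, -2.07 and -1.53. The gene ftr01 stood at 0.0951 ± 0.0652 CPM, from 3 and 10 counts, against 18.5 ± 0.316.

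In all, edgeR called 48 genes in brain, of which 22 rose and 26 fell, and 4892 genes had an unadjusted p under 0.05 where 1096 were expected. The count was 0 without control 1 (4649 genes at an unadjusted p under 0.05) and 0 without control 2 (3250 genes), 127 without mutant 1 and 164 without mutant 2. Without 1 library all 48 genes kept their sign, with log2 fold changes of 0.880 to 1.501 times those from all 4 libraries, and without control 1 or control 2 taco1 stood at 8.04 and 8.16 and KHK at 7.33 and 6.59. The median SE of the 48 genes went from 0.194 to 0.217 and 0.210 without control 1 and 2, and to 0.223 and 0.219 without mutant 1 and 2. The prior degrees of freedom of the edgeR fit went from 3.43 to 2.65 and 2.72 without a control, and to 4.69 and 4.58 without a mutant library. The biological coefficient of variation was 0.283 without either control and 0.192 without either mutant library, and why the calls ended was not tested. DESeq2 called 2336 genes and limma-voom 40.

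Activity-dependent immediate early genes, which neurons induce on firing, were mostly lower in mutant brain. Of 49 members, 0 were called over all genes, while 3 rose and 19 fell adjusted over the list alone, with a median log2 fold change of -0.39 (camera adjusted p = 1.29e-07, and adjusted p = 0.798 with an estimated correlation). DUSP2 stood at -1.87 (SE 0.22) and NPAS4 ENSDARG00000055752 at -1.14 (SE 0.15), each with an adjusted p of 0.0608 over all genes. JUN, IER5L and crema went the other way, at 0.66, 0.84 and 0.56, and IER5L had the smallest p of the list. These members were chosen after their values were seen, as were those named below from lists without a call over all genes. Without control 1 the number that fell over the list alone was 6, and without mutant 1 it was 9.

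Gene lists of protein synthesis and energy metabolism had medians below 0 in mutant brain, by small amounts. Of 58 cytosolic ribosomal protein genes, 0 were called over all genes and 45 fell adjusted over the list alone, with a median of -0.33 (camera adjusted p = 5.25e-19). For oxidative phosphorylation 1 of 49 fell over the list alone, with 48 below 0 and a median of -0.29, or -0.18 without mutant 1 (6.19e-09), and for mitochondrially encoded genes 8 of 13 fell (6.4e-07). Mitochondrial transcripts made up 9.69% and 10.2% of counts in mutant brain, and 11.97% and 12.5% in control brain. For hypoxia and glycolysis 12 of 58 fell over the list alone (3.07e-05), and for the glucocorticoid response 2 rose and 9 fell of 34 (0.00124), with FKBP5 at -1.50 (SE 0.33). Each of these lists had adjusted p = 0.798 with an estimated correlation.

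Lists for voltage-gated calcium channels, potassium channels and glutamatergic synapses passed upward in mutant brain with camera, while those for voltage-gated sodium channels and for GABAergic and glycinergic synapses did not, and cell type markers passed in no list. Astroglia and radial glia markers summed to 11478 and 11459 CPM in mutant and to 12928 CPM in each control library, with a median of -0.18, and neutrophil markers to 123.1 and 114 against 144 and 153, also at -0.18 and at -0.37 and -0.06 without mutant 1 and 2 (camera adjusted p = 0.186 each). Pan-neuronal markers had a median of 0.10, or 0.04 without control 1 (0.325). Of 34 voltage-gated calcium channel genes 30 lay above 0, with a median of 0.33, or 0.20 without control 2, and 0 called over all genes or over the list alone (camera adjusted p = 0.000237). Of 12 voltage-gated sodium channel genes 9 lay above 0 (camera adjusted p = 0.141) and of 44 GABAergic and glycinergic synapse genes 28 (0.202), with 0 called over all genes or over the list alone in both. Of 56 potassium channel genes 1, KCNJ13, fell over all genes, and 5 rose and 2 fell over the list alone (0.00182). Of 47 glutamatergic synapse genes 5 rose and 2 fell over the list alone (0.00255), and of 45 neurotrophic factor genes 10 rose and 1 fell (0.0134). Neuropeptide genes leaned downward, with 36 of 43 below 0 and 1 that fell over the list alone (0.00542). The unfolded protein list had 1 fall over all genes, ERO1A, and 4 over the list alone of 39 (0.000768). Fgf pathway genes had 3 falls over the list alone of 30 (0.0168), and cholesterol synthesis genes 1 rise and 2 falls of 37 (0.0152). Each of these lists had adjusted p = 0.798 with an estimated correlation.

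The comparison of uninjured fin asks whether the genotypes differed without injury, after the same 36 hours at 33 °C as amputated fin. The genes with the smallest p were the keratin gene krt93, at 89.5 ± 13.4 CPM in mutants against 185 ± 13.3 in controls (log2 fold change -1.05, SE 0.15), the histamine receptor gene hrh3 (-0.99, SE 0.17), si:rp71-1g18.1 (1.36, SE 0.23), the phosphatase gene DUSP5 (-1.20, SE 0.21) and OXER1 (-0.85, SE 0.15). None of these passed with edgeR, each with an adjusted p of 0.702, while all 5 passed with DESeq2. The edgeR test called 0 genes, with 1499 at an unadjusted p under 0.05 where 1061 were expected, limma-voom called 0 and DESeq2 26. Without uninjured mutant 2 the edgeR count was 1, and without uninjured control 2 it was 2.

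Immediate early genes had a median of -0.31 in uninjured mutant fin, with 34 of 42 below 0 and 1, DUSP5, that fell adjusted over the list alone (camera adjusted p = 0.000148, and adjusted p = 0.499 with an estimated correlation). Oxidative phosphorylation genes lay below 0 in 46 of 49 members with a median of -0.15 (1.69e-05), and ribosomal protein genes in 57 of 59, also at -0.15 (0.000148). Matrix remodelling genes had a median of -0.14 (0.00454) and retinoic acid pathway genes -0.28 (0.00465). Glucocorticoid response genes had a median of -0.26 (0.00346), unfolded protein genes -0.16 (0.00465), heat shock genes -0.13 (0.0219) and cell division genes -0.17 (0.0278). In each of these 8 lists 0 genes were called over all genes and adjusted over the list alone. The lists for oxidative phosphorylation, matrix remodelling, retinoic acid and glucocorticoids had adjusted p = 0.785 with an estimated correlation, and the other 4 had adjusted p = 0.795 with an estimated correlation. Without 1 library the number of immediate early genes that fell over the list alone was 7 (uninjured mutant 2), 3 (uninjured mutant 1), 3 (uninjured control 2) or 0 (uninjured control 1). The median of that list was -0.16 with 27 of 43 below 0 without uninjured control 2, and -0.21 with 26 of 42 below 0 with library size as the scaling. Without uninjured control 2 the median of cell division genes turned to 0.13, and without uninjured mutant 1 the medians were -0.06 for ribosomal proteins, -0.08 for matrix, -0.10 for retinoic acid, -0.02 for unfolded protein and -0.07 for heat shock. For glucocorticoids it was -0.15 without uninjured control 1. Library size as the scaling moved the median of all genes to 0.08, and the medians of the lists for oxidative phosphorylation, ribosomal proteins, matrix, unfolded protein, heat shock and cell division to between -0.08 and -0.04.

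At 36 hpa the comparison asks how the early regenerate of mutants differed from that of controls. CCNG2, an atypical cyclin gene, stood at 22.4 ± 1.76 CPM in mutants against 65.5 ± 1.32 in controls (log2 fold change -1.55, SE 0.11, adjusted p = 0.0117). CEBPB, a transcription factor gene of the acute phase response, stood at 75.5 ± 0.586 against 181 ± 14.7 (-1.26, SE 0.12, adjusted p = 0.0413). These 2 genes fell and no gene rose. The genes next in rank did not pass, with an adjusted p of 0.0922 each: BTG2 at -2.38 (SE 0.28), si:dkey-238i5.2 at -0.97 (SE 0.11) and CREB5 ENSDARG00000099002 at -2.04 (SE 0.24). These 3 passed with limma-voom, DESeq2, no low count filter and the 4 libraries compared. They did not pass with the other scalings or with 12 libraries in 1 fit.

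Immediate early genes were lower in mutant fin at 36 hpa as a group. Of 42 members, 0 were called over all genes, and 22 fell and 1 rose adjusted over the list alone, with 38 below 0 and a median of -0.87. The antiproliferative gene BTG2 stood at 32.8 ± 5.76 CPM against 171 ± 28.0. The phosphatase genes DUSP5 and DUSP1 stood at -1.67 (SE 0.21) and -1.43 (SE 0.28), and the AP-1 genes JUN and JUND at -1.01 (SE 0.14) and -1.25 (SE 0.16). FOSB, egr1 and NR4A1 stood at -2.13, -1.32 and -1.31. IER5L went the other way, at 0.56. Against the mean of the controls, the median over the list was -0.77 in mutant 1 and -0.76 in mutant 2. This list passed with camera (adjusted p = 2.78e-32), with an estimated correlation (adjusted p = 0.0111) and with fry (adjusted p = 0.0125). With 1 library left out its median ranged from -0.91 to -0.78, and the number that fell over the list alone was 6 without 36 hpa mutant 1, 6 without mutant 2 and 10 without control 2.

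**Figure D2:**
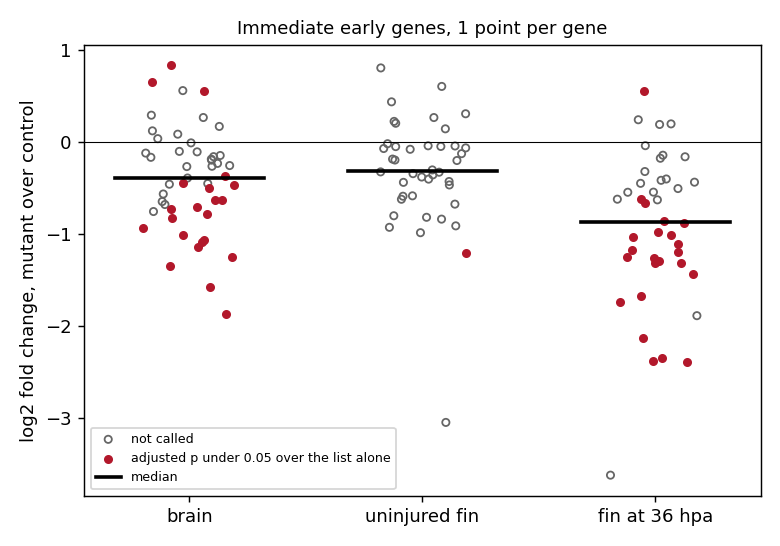
Log2 fold change of mutant over control for each tested immediate early gene in brain, uninjured fin and fin at 36 hpa, with filled points for an adjusted p under 0.05 over the list alone and a bar at the median. The medians are -0.39, -0.31 and -0.87.

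Clock genes were set beside this list at 36 hpa. The 37 clock genes that are not on the immediate early list had a median absolute log2 difference of 0.300, with 0 called adjusted over the list alone. The full circadian list had 0 calls over all genes and 1 rise and 3 falls over the list alone of 39 (camera adjusted p = 3.36e-06, and adjusted p = 0.218 with an estimated correlation). The glucocorticoid list had 1 fall over all genes, CEBPB, and 1 rise and 7 falls over the list alone of 32, with CEBPD at -1.56 (SE 0.29) and KLF9 at -1.86 (SE 0.35) (8.38e-09, and adjusted p = 0.218 with an estimated correlation). Notch pathway genes leaned upward, with 0 calls over all genes and 5 rises over the list alone of 26, among them HEY1 at 0.88 and LFNG at 0.61 (0.000107, and adjusted p = 0.415 with an estimated correlation).

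Macrophage genes had 0 calls over all genes or over the list alone, with 31 of 37 above 0 and a median of 0.20 (camera adjusted p = 0.000781, and adjusted p = 0.675 with an estimated correlation). Red blood cell genes had a median of 0.86, or 0.03 with 8 of 14 above 0 without 36 hpa mutant 1, with 0 calls over all genes or over the list alone (0.000556, and adjusted p = 0.675 with an estimated correlation). Hemoglobin transcripts made up 0.0116% of counts in 36 hpa mutant 1 and 0.00209% in mutant 2, against 0.00212% and 0.00298% in the controls. Blastema and fin regeneration genes had a median of 0.04, or 0.16 without 36 hpa control 2, with 0 of 47 called over all genes or over the list alone. Unfolded protein genes had 1 fall, CEBPB, over all genes and over the list alone of 39, with a median of -0.11 (0.000781, and adjusted p = 0.675 with an estimated correlation). In the p53 list 1 gene, CCNG2, fell over all genes and 4 over the list alone of 34 (0.00648, and adjusted p = 0.236 with an estimated correlation), and its median of -0.00 turned above 0 with library size as the scaling and was -0.13 and 0.03 without 36 hpa mutant 1 and 2, while its mean was -0.15. DNA replication genes had a median of -0.15, or -0.03 without 36 hpa control 1, with 0 of 42 called in either way (0.016, and adjusted p = 0.824 with an estimated correlation).

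The edgeR count at 36 hpa was 2, with 1549 genes at an unadjusted p under 0.05, and both genes lost their call without any 36 hpa library. The count was 0 without 36 hpa mutant 1, mutant 2, control 1 or control 2 (1059, 930, 1094 and 1269 genes at an unadjusted p under 0.05), while CCNG2 kept a log2 fold change of -1.63 to -1.47 and CEBPB of -1.34 to -1.17. Their SE rose from 0.11 and 0.12 to at least 0.149 in each case. The count was 29 and 31 without uninjured mutant 1 and 2, and 10 without uninjured control 1 and also without uninjured control 2. By limma-voom it was 8, by DESeq2 258 and from the 4 libraries alone 91.

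The amputation comparison in control fin asks which genes change by 36 hpa. Genes of the regenerating fin fold and blastema rose steeply. The actinotrichia genes and1 and and2 went from 4.47 ± 0.292 to 2547 ± 313 CPM and from 0.0375 ± 0.0530 to 756 ± 82.0 CPM. The matrix gene TNC ENSDARG00000021948 rose by a log2 fold change of 7.43 (SE 0.26), the cytokine gene il11a by 6.25 (SE 0.56), vcana by 4.78 (SE 0.25) and FGF20 ENSDARG00000007356, a signal of blastema formation, by 4.80 (SE 0.19). Of 47 blastema and fin regeneration genes 36 rose and 3 fell over all genes, and 37 rose and 3 fell adjusted over the list alone (camera adjusted p = 3.29e-25, and adjusted p = 0.0566 with an estimated correlation).

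Cell division genes rose together in control fin: 40 of 42 rose over all genes and 40 adjusted over the list alone, among them plk1 at 2.69 (SE 0.18) and chaf1a at 2.89 (SE 0.16) (camera adjusted p = 6.25e-31, and adjusted p = 0.323 with an estimated correlation). Matrix remodelling had 32 rises and 7 falls of 50 over all genes and 33 and 7 over the list alone (3.36e-13, and adjusted p = 0.183 with an estimated correlation). In the Wnt pathway 20 rose and 5 fell of 37, or 22 and 6 over the list alone, with LEF1 at 2.81 (SE 0.22) and WNT11 at -3.05 (SE 0.19) (0.00312, and adjusted p = 0.183 with an estimated correlation). In the Fgf pathway 15 rose and 4 fell of 27, the same numbers over the list alone, with ETV4 at 2.29 (SE 0.12) and FGF3 at 3.27 (SE 0.25) (0.0018, and adjusted p = 0.183 with an estimated correlation). In the Hedgehog pathway 12 rose and 1 fell of 19, or 13 and 1 over the list alone, with SHH ENSDARG00000068567 at 5.18 (SE 0.52) (0.00422, and adjusted p = 0.34 with an estimated correlation). Macrophage genes had 23 rises and 4 falls of 37, or 24 and 4 over the list alone, with ccl34b.1 at 3.12 (SE 0.19) and SPI1 at 1.35 (SE 0.13) (0.000914, and adjusted p = 0.549 with an estimated correlation).

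Epidermis genes fell in control fin, and so did single genes of other tissues. The keratin genes krt91 and krt15 stood at -2.23 (SE 0.09) and -2.31 (SE 0.16), and of 37 epidermis genes 25 fell and 4 rose, or 26 and 4 over the list alone (camera adjusted p = 7.76e-07, and adjusted p = 0.34 with an estimated correlation). The muscle creatine kinase gene ckma fell by a log2 fold change of -6.25 (SE 0.41), foxn1 by -5.89 (SE 0.53), the mineralisation inhibitor gene mgp by -4.94 (SE 0.33) and sult1st4 by -5.30 (SE 0.35), while ACP5, an osteoclast gene, rose by 3.88 (SE 0.22). The lists that hold mgp and ckma did not follow them: of 33 bone genes 12 rose and 5 fell, or 13 and 5 over the list alone (median 0.59, or 0.38 without 36 hpa control 2, camera adjusted p = 0.155), and of 20 muscle genes 2 rose and 2 fell, or 1 and 1 over the list alone (median -0.17, or 0.18 without uninjured control 2 and 0.05 with library size as the scaling, 0.496). Of 59 ribosomal protein genes 39 fell over all genes and 41 over the list alone, with a median of -0.39 (0.00166, and adjusted p = 0.759 with an estimated correlation). Circadian genes split, with 14 rises and 13 falls of 39, or 14 and 14 over the list alone. PER1 ENSDARG00000012499 rose by 6.18 (SE 0.26) and NR1D2 by 5.80 (SE 0.16), while CLOCK ENSDARG00000011703 fell by -1.47. The median of this list was -0.10 with a mean of 0.93, camera gave an upward direction, and library size as the scaling turned the median to 0.12, as did leaving out uninjured control 1, to 0.09 (0.0055, and adjusted p = 0.34 with an estimated correlation).

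In control fin edgeR called 9430 genes, of which 4887 rose and 4543 fell, or 51.8% up. With library size alone as the scaling 66.4% were up and the median over all genes moved to 0.21. Without 36 hpa control 2 the count was 6117, and with an absolute log2 fold change of at least 1 it was 5676.

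Mutant fin was compared in the same way, to ask which genes amputation changes in the mutant. The fin fold genes and1 and and2 went from 5.86 ± 0.0604 to 2526 ± 99.4 CPM and from 0 to 882 ± 6.42 CPM, the latter at least 37678-fold higher. TNC ENSDARG00000021948 rose by 7.33 (SE 0.25), il11a by 6.76 (SE 0.57), vcana by 5.49 (SE 0.26) and FGF20 ENSDARG00000007356 by 4.18 (SE 0.19). Of 47 blastema and fin regeneration genes 37 rose and 3 fell, or 38 and 3 adjusted over the list alone, and this list also passed with an estimated correlation (camera adjusted p = 1.75e-27, and adjusted p = 0.0479 with an estimated correlation). Of 42 cell division genes 40 rose, or 41 with 1 fall over the list alone, with plk1 at 2.96 (SE 0.18) (2.36e-29, and adjusted p = 0.399 with an estimated correlation). Matrix remodelling had 34 rises and 7 falls of 50, or 38 and 7 over the list alone (2.92e-15, and adjusted p = 0.163 with an estimated correlation).

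Of the signalling lists, Wnt, Fgf and Hedgehog passed upward in mutant fin, while Notch (median -0.30, 5 rises and 11 falls of 26, the same over the list alone, camera adjusted p = 0.53), Bmp, activin and Tgf-beta (0.50, or 0.27 without uninjured mutant 1, 18 and 7 of 41, or 19 and 7 over the list alone, 0.055) and retinoic acid (0.15, or 0.07 and 0.46 without uninjured mutant 1 and 2, 6 and 3 of 23, the same over the list alone, 0.531) did not pass. In the Wnt pathway 22 rose and 5 fell of 37, or 22 and 6 over the list alone, with LEF1 at 3.12 (SE 0.23) (camera adjusted p = 0.00418, and adjusted p = 0.198 with an estimated correlation). In the Fgf pathway 14 rose and 3 fell of 27, the same over the list alone, with FGF3 at 4.37 (SE 0.26) (0.000403, and adjusted p = 0.163 with an estimated correlation). In the Hedgehog pathway 12 rose and 1 fell of 19, the same over the list alone, with SHH ENSDARG00000068567 at 6.61 (SE 0.55) (0.00848, and adjusted p = 0.458 with an estimated correlation). The retinoic acid synthesis gene ALDH1A2 rose by 3.68 (SE 0.24). Heat shock genes had 25 rises and 1 fall of 42, or 28 and 1 over the list alone (3.6e-05, and adjusted p = 0.458 with an estimated correlation). Macrophage genes had 24 rises and 3 falls of 37, the same over the list alone (0.000111, and adjusted p = 0.497 with an estimated correlation). Epidermis genes had 25 falls and 5 rises of 37, or 26 and 5 over the list alone, with krt91 at -2.15 (SE 0.09) and krt15 at -2.36 (SE 0.16) (4.84e-05, and adjusted p = 0.476 with an estimated correlation). The genes ckma, foxn1 and mgp fell by log2 fold changes of -6.73, -5.95 and -5.76.

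In mutant fin edgeR called 9612 genes, of which 4997 rose and 4615 fell, or 52.0% up, against 60.9% with library size as the scaling. Without 36 hpa mutant 2 the count was 6177, and with an absolute log2 fold change of at least 1 it was 5836. With library size alone the median over all genes moved to 0.11.

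The last comparison asks whether the amputation response differed between the genotypes. Across 21220 genes, which are not independent replicates, the log2 fold changes of the responses correlated with a Pearson r of 0.862 and a Spearman rho of 0.879, and the slope by total least squares was 0.995. Among the 11643 genes with a mean of at least 5 CPM r was 0.959. Both responses shared 4075 rises where 1151 were given by independence, and 3584 falls where 988 were, and 3 genes were called in opposite directions. The genes with the smallest p of the difference did not pass with edgeR: hrh3, with responses of 3.79 in control and 5.46 in mutant fin (difference 1.67, SE 0.21, adjusted p = 0.802), abcc6a (0.93, SE 0.15), SLC46A2 (-1.42, SE 0.23), CCNG2 (-0.95, SE 0.16) and CEBPB (-0.996, SE 0.17), the last 4 with an adjusted p of 0.955. With DESeq2 all 5 passed.

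**Figure D3:**
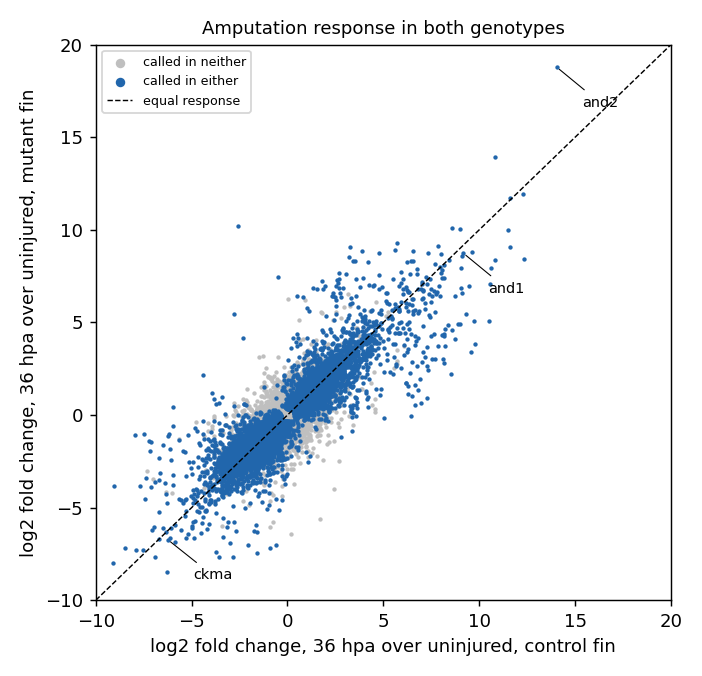
Log2 fold change of 36 hpa over uninjured fin in control fin (x axis) and in mutant fin (y axis), with 1 point per tested gene, blue where edgeR called the gene in either genotype. The points follow the line of equal response, with r at 0.862 across 21220 genes, and the fitted value of and2 in mutant fin rests on an uninjured level of 0.

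The difference of responses lay below 0 for most immediate early genes: of 42, 0 were called over all genes and 3 fell adjusted over the list alone, with a median difference of -0.49, and with the pool tag as a block 10 fell and 1 rose with a median of -0.47 (camera adjusted p = 6.3e-09, and adjusted p = 0.14 with an estimated correlation). By genotype, 15 of these genes rose and 8 fell on amputation in control fin, and 12 rose and 17 fell in mutant fin, with the same numbers adjusted over the list alone. JUN fell in both, by -1.76 (SE 0.15) in control and -2.72 (SE 0.15) in mutant fin. Circadian genes had a median difference of -0.31, or -0.06 without uninjured mutant 2, with 0 called over all genes and 1 fall over the list alone (0.00122, and adjusted p = 0.562 with an estimated correlation). Neutrophil genes had a median difference of 0.47, or 0.27 without 36 hpa control 2, with 15 of 18 above 0 and 0 called over all genes or over the list alone (0.00382, and adjusted p = 0.562 with an estimated correlation). Notch (0.20, adjusted p = 0.0126), heat shock (0.20, 0.0174), ribosomal protein (0.16, 0.0103), oxidative phosphorylation (0.14, 0.0163), hypoxia (0.14, 0.0254) and red blood cell genes (0.83, 0.0104) had positive medians with 0 called in either way, and none passed with an estimated correlation (adjusted p = 0.636 or more with an estimated correlation). Red blood cell markers summed to 199.9 CPM in 36 hpa mutant 1, against 73.6 in mutant 2, 68.6 and 81.3 in the 36 hpa controls and 48.0 to 63.5 in uninjured fin, and the median difference of this list was -0.01 without 36 hpa mutant 1. Without uninjured control 1 it was -0.01 for hypoxia and 0.23 for oxidative phosphorylation, and without uninjured mutant 1 it was 0.11 for heat shock and 0.04 for ribosomal proteins. With library size as the scaling the medians of the lists for Notch, heat shock, ribosomal proteins, oxidative phosphorylation and hypoxia were 0.05 to 0.12. The number that fell over the list alone among immediate early genes was 0 without 36 hpa mutant 1, mutant 2 or control 2, 1 without uninjured control 1, 2 without uninjured control 2, 6 without 36 hpa control 1, and 8 and 7 without uninjured mutant 1 and 2. For the difference of responses edgeR called 0 genes, with 999 at an unadjusted p under 0.05 where 1061 were expected, limma-voom called 0 and DESeq2 27.

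Genotype calls were then compared between tissues, which also differed in time at 33 °C (1 day for brain and 36 hours for fin). Brain and uninjured fin, brain and fin at 36 hpa, and uninjured and 36 hpa fin shared 0 edgeR calls. At an unadjusted p under 0.01 brain and uninjured fin shared 18 higher genes where independence gave 6.47 (Fisher's exact p = 8.27e-05) and 10 lower genes where it gave 3.59 (Fisher's exact p = 0.00316). Brain and fin at 36 hpa shared 14 higher genes against 7.86 (Fisher's exact p = 0.04) and 25 lower genes against 8.20 (Fisher's exact p = 7.56e-07). In opposite directions they had 6 and 16 genes, for uninjured and 36 hpa fin. The values from independence assume that brain and fin libraries came from different fish, which the sources do not say. Fisher's exact test also takes genes as independent units, which genes measured in the same libraries are not. Uninjured and 36 hpa fin shared 29 higher genes against 1.60 and 11 lower genes against 1.17, and their libraries share pool tags. Of the 33 brain calls placed on a chromosome, 1, R3HDM2, lay on that of scn8ab, or 3.03% against 4.31% of tested genes (Fisher's exact p = 1, two-sided).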

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

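The tests of tissue difference, of brain calls in fin and of the share of calls on other chromosomes were chosen after the brain calls were seen, and the odds ratio for the chromosome of scn8ab was planned.

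The genotype effect of 3 genes named in brain differed from that in fin, in 1 edgeR fit of all 12 libraries with the difference of the effects tested. Brain was held for 1 day at 33 °C and fin for 36 hours, so tissue and time at 33 °C cannot be told apart here. For CDC45 the brain effect minus the fin effect was 5.45 in log2 units against uninjured fin (SE 0.41, adjusted p = 0.00165) and 5.34 against fin at 36 hpa (SE 0.41, adjusted p = 0.0017). For SERPINH1 ENSDARG00000019949 it was 3.37 (SE 0.28, adjusted p = 0.00283) and 3.57 (SE 0.28, adjusted p = 0.0017), and for ERO1A it was -2.50 (SE 0.30, adjusted p = 0.0213) and -2.80 (SE 0.30, adjusted p = 0.00925). CDC45 rose in mutant brain and lay below 0 in mutant fin, at -0.66 uninjured and -0.55 at 36 hpa. Over 24053 genes, 20 differed against uninjured fin and 24 against fin at 36 hpa.

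The 48 brain calls, with several genes near 0 in 1 genotype, may reflect alleles that came with the mutant line. Alleles linked to scn8ab are argued against as the source of most calls, since 32 of the 48, or 66.7%, were placed on other chromosomes and 1 was on that of scn8ab. That 0 were among the 50 nearest placed genes decides nothing, with an odds ratio of 0 (95% interval 0 to 37.1). For the 1 call on that chromosome and the 15 not placed, linked alleles stay open. The odds ratio for the chromosome was 0.694 (95% interval 0.0170 to 4.17) from 68.8% of the calls. It was 1.04 (0.768 to 1.39) at an unadjusted p under 0.01, a wider set that dilutes the calls. Alleles at the called genes themselves stay open as well: the median difference of 45 brain calls in fin, in the brain direction, was 0.208 uninjured (33 of the same sign) and 0.0426 at 36 hpa (24), which met the bound written against them, but it was set aside after the value was seen because the sources do not say whether brain and fin came from the same fish, and ftr01 lay at -8.27 and -4.64 in fin (edgeR with Benjamini-Hochberg adjusted p = 0.705 and 0.809). An effect of the genotype on brain is untested, and it cannot be told apart from alleles at the called genes.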

How the results depend on the processing

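All alternatives in this part were planned. The amputation counts kept their size under RLE, library size, no low count filter, limma-voom, DESeq2, 12 libraries, 4 libraries and the pool block, from 8113 to 9830 in control and 9593 to 10067 in mutant fin. With an absolute log2 fold change of at least 1 they were 5676 and 5836, which follows from the added condition. With 1 library left out they ranged from 6117 to 9373 and from 6177 to 10295, where fewer libraries also mean fewer residual degrees of freedom. The genotype counts were small and moved more. In brain 48 became 387 with no low count filter, 2336 with DESeq2, 267 with 12 libraries in 1 fit and 0 to 164 with 1 library left out. In uninjured fin 0 became 26 with DESeq2 and 0 to 2 with 1 library left out. At 36 hpa 2 became 98 with no low count filter, 8 with limma-voom, 258 with DESeq2, 1 with 12 libraries, 91 with the 4 libraries compared and 0 to 31 with 1 library left out. For the difference of responses 0 became 27 with DESeq2. With 1 library left out the called genes of brain and 36 hpa kept their sign, which is no separate support, since they were called from the same libraries. For these counts the cause was not tested.

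Lists past the threshold with camera, with an estimated correlation and with fry numbered 15, 0 and 0 in brain, 9, 0 and 0 in uninjured fin, 9, 1 and 1 at 36 hpa, 14, 0 and 28 for amputation in control fin, 12, 1 and 29 in mutant fin, and 9, 0 and 0 for the difference of responses. Fry tests each list on its own and camera tests it against other genes. The correlation of responses ranged from 0.723 (without uninjured control 1) to 0.781 with 1 library left out. Overlaps at an unadjusted p under 0.01 numbered 28 for brain and uninjured fin, 39 for brain and fin at 36 hpa and 40 for uninjured and 36 hpa fin, against 0, since that threshold admits more genes. The share on the chromosome of scn8ab at 36 hpa was 5.66% against 0 and in brain 4.47% against 3.03%, and the cause was not tested.

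SCN8A ENSDARG00000018032 in brain passed with DESeq2, at 0.37 (adjusted p = 0.0269). SCN8A ENSDARG00000005775 in brain ranged from 0.00543 to 0.299 with 1 library left out. In fin, with 8 to 26 counts per library, the sign of ENSDARG00000018032 was not stable and the cause was not tested. With 1 library left out it ranged from -0.73 to 0.28 in uninjured fin (0.28 and 0.22 where the sign turned), from -0.56 to 0.45 at 36 hpa (0.10 and 0.45), from -0.12 to 0.89 for amputation in control fin, and from -0.43 to 0.58 for the difference of responses (0.23, 0.58, 0.58 and 0.25). That difference was -0.01, and 0.15 with limma-voom, 0.0234 with 12 libraries and 0.0881 with the pool block. Of the named genes called in brain, 0 of 17 kept their call under every alternative, against 166 of 179 for amputation in control and 163 of 181 in mutant fin. Title numbers shared across genotypes correlated at 0.125, -0.0104 and -0.0546, and a block on them gave 32 brain calls, 26 shared with the 48, and 3 at 36 hpa.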

Other observations

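All tests of explanations in this part were chosen after the result was seen, and the list counts were planned.

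Further groups moved with amputation. Of 21 T and B cell genes 11 fell and 2 rose in control fin, and 10 fell and 1 rose in mutant fin, with the same numbers adjusted over the list alone, and ZAP70, a T cell kinase gene, stood at -2.01 (SE 0.27) and -1.71 (SE 0.26). The camera adjusted p was 0.0259 in control fin (adjusted p = 0.491 with an estimated correlation) and 0.055 in mutant fin. Of 37 cholesterol synthesis genes 16 fell and 2 rose in control fin, or 16 and 3 over the list alone (0.0426, and adjusted p = 0.553 with an estimated correlation), and 13 fell and 7 rose in mutant fin, the same over the list alone (0.0901). Oxidative phosphorylation had 26 rises and 2 falls of 49 in control fin, the same over the list alone (0.0225, and adjusted p = 0.553 with an estimated correlation) and 31 rises and 1 fall in mutant fin, or 33 and 1 over the list alone (0.00117, and adjusted p = 0.497 with an estimated correlation). Heat shock genes had 17 rises and 2 falls of 42 in control fin, the same over the list alone (0.00166, and adjusted p = 0.491 with an estimated correlation). Fibroblast genes had 15 rises and 8 falls of 28 in mutant fin, or 16 and 9 over the list alone, and mitochondrially encoded genes 9 rises and 1 fall of 13, the same over the list alone (0.0316 each, and adjusted p = 0.558 with an estimated correlation). The neurotrophic receptor gene gfra3 was at 0 in uninjured fin and at least 363-fold higher at 36 hpa in control and at least 326-fold higher in mutant fin. The potassium channel gene KCNJ3 ENSDARG00000062217 fell by log2 fold changes of -3.90 (SE 0.36) and -3.25 (SE 0.35), and the calcineurin regulator gene RCAN2 rose by 2.45 (SE 0.16) and 2.05 (SE 0.15).

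The lower immediate early genes of mutant fin at 36 hpa were set against 3 technical explanations. A lower share of 1 listed cell type would lower its marker list as far, but the lowest median of 14 marker lists, that of endothelium, was -0.0882 against -0.87. This argues only against cell types that have a list, and other cell types or cell states stay open. Library scaling moves every gene of a library alike, but the list median minus the median of all tested genes was -0.875, and -0.916 to -0.794 with 1 library left out. Collection of mutant and control fins at different times of day stays open and is a candidate explanation, since the median absolute difference of 37 clock genes off the list, 0.300, lay at percentile 99.88 of 10000 random lists of like expression (median 0.162), although random lists ignore that clock genes move together. The immediate early list was also lower in mutant brain (median -0.39) and uninjured mutant fin (-0.31), where the circadian list did not pass (camera adjusted p = 0.234 and 0.984). Over the list alone, 4 circadian genes rose and 6 fell in brain, and 1 rose and 0 fell in uninjured fin. Camera tests for a shared direction and can miss clock genes that split up and down. Its result there thus does not argue against a difference in time of day. The test of absolute differences was not run in brain or uninjured fin. An effect of the genotype stays open too, and the sources used here give no collection times. Other technical explanations were not tested.

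Clock genes after amputation were set against collection of amputated and uninjured fins at different times of day. The 6 activator genes (the BMAL, CLOCK and NPAS2 family) had a median log2 fold change of -0.888 in control and -1.61 in mutant fin, and the 17 output genes 1.08 and 1.02. Opposite arms in both genotypes are consistent with a difference in time of day, though output genes were not uniform, with 10 rises and 4 falls in control and 9 and 6 in mutant fin. An effect of amputation on the clock was not separated from it and stays open.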
